A study of Homo sapiens with 6 samples.

How the data were processed

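RNA was sequenced from SKMEL28, a pigmented human melanoma line (wild type), and from SK-P8-2, its counterpart with a miR-211 deletion, grown in culture and as xenografts in SCID mice. Per the labels' protocols, xenografts were flash frozen, total RNA was extracted with Trizol, libraries were made with an Illumina TruSeq RNA kit and sequenced on a HiSeq 2500. The labels list 6 libraries in 4 groups, 1 library per line in culture and 2 xenografts per line. TopHat2 2.1.1, Partek and the hg38 genome build are named in the submitters' processing notes. How reads were assigned to transcripts, whether strand was used, and whether mouse reads were removed from the xenografts are not given in the sources used here.

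The authors deposited 1 table for cells and 1 for xenografts, each with 57949 RefSeq transcripts of 23148 gene symbols. Per the file headers, each table holds estimated counts of reads for 1 column per line, and whether a deposited xenograft column holds 1 xenograft of a line or both combined is not given in the sources used here. The deposited estimated counts were whole for 96.6% to 97.0% of transcripts of genes with 1 transcript and for 5.69% to 10.0% of those of genes with more, so reads were divided between transcripts of a gene. Per the file headers, the tables also hold RPKM values. The column sums made 72.9% and 61.7% in wild-type and deletion-line xenografts, and 84.0% and 84.9% in cells, of the read totals that the authors' RPKM values imply. The authors also deposited a log2 fold change, a p-value and an FDR per transcript. The tool is not given in the sources used here. The deposited p-values were compared with those of the exact test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on counts rounded to whole numbers, with TMM factors and a fixed dispersion. All columns were used, and 0 columns of other samples were present.

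The estimated counts of a gene's transcripts were summed per symbol and divided by the column total to give CPM. The log2 ratio of deletion line over wild type was taken on CPM + 1, and plain folds with intervals are ratios of CPM. Expected counts were rounded to whole reads for intervals, which are exact 95% Clopper-Pearson intervals of the share of 2 columns' reads converted to a ratio. A count of up to 3 reads was taken as the floor, equal to 0.0470 and 0.0628 CPM in wild-type and deletion-line xenografts and 0.0707 and 0.0713 CPM in cells. Small structural RNAs took 10.4%, 8.28%, 8.11% and 8.56% of the reads of the columns in the same order. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A total of 23 symbols per file had been turned into dates, and they were kept as features and not named.

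Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The xenografts were to be tested with edgeR's quasi-likelihood test and limma's camera and fry. With 1 column per line no residual spread exists, so neither these nor DESeq2, voom, the replicate block, leaving out a xenograft or an interaction test were run. The rule set for the cells was used for both tables instead. It counts genes at least 2-fold different on the CPM + 1 scale with a mean of at least 5 CPM. In a total of 44 gene lists, covering miR-211 targets, melanoma programmes, signalling, metabolism, stress, cell cycle, immunity, matrix, sample quality and host cell types, lists with at least 5 such genes were described by the percentile of their median among 10000 random lists of the same size matched on mean expression in 10 bins. The bounds were the 2.5th and 97.5th percentiles. The mitochondrially encoded list had 0 genes in the tables. The percentile describes these columns and is no p-value. Cell type lists overlap with the line, since SKMEL28 itself expresses several members such as CD68 and PERP.

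The rule for xenografts asked for a test across replicates, which could not be run, so the rule set for cells was used there with 4 members per list kept. Named genes were the 10 highest and the 10 lowest log2 ratios per table among genes with a mean of at least 5 CPM, without clone, small RNA, pseudogene and antisense names. TRPM1, MITF, PDK4, POU3F2, KCNMA1, TGFBR2, IGF2R and DUSP6 were always named. Each list outside the bounds also gave its members with the largest ratio in its direction, 4 in xenografts and 3 in cells, of which some members are not reported here. Other genes were chosen after their values were seen, namely those given as CPM for the muscle and stromal markers and the genes shared by both tables.

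Cells and xenografts were compared by correlation across genes with a mean of at least 5 CPM in both. Sites for miR-211-5p, at bases 2 to 8 of the mature sequence, were searched in the 3' UTRs of GENCODE 29 (hg38), with a site difference taken within bins of 3' UTR length and 100000 permutations, and with a pair of shuffled control sites. The build named for the authors' files is the same, and 94.3% and 94.9% of expressed genes in xenografts and cells had an annotated 3' UTR. Transcript GC content was found for 98.5% and 98.7% of genes.

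The steps were tested on simulated data. For xenografts (10780 genes, 50 changed genes per fold), the 2-fold rule found 6% of genes changed by 1.5-fold, 46% at 2-fold, 98% at 3-fold and 100% at 4-fold, and passed 5 of 10586 unchanged genes. For cells (10693 genes) it found 6%, 58%, 100% and 100% at those folds and 1 of 10499 unchanged genes. The simulated spread equalled dispersions of 0.0198 and 0.0178, taken from the real ratios. Of lists with no effect, 3.43% in xenografts (10813 genes) and 5.88% in cells (10713 genes) fell outside the bounds, and 5 of 5 lists shifted by a log2 of 0.35 did so in each. Genes were drawn independently and without a length trend, so lists of genes that vary together were not covered.

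Alternatives tried were other pseudocounts, scalings (TMM, RLE, upper quartile, median centring), expression filters, fold rules, the authors' own folds and calls, and the host and matrix lists left out. Added after the data were seen were RPKM values, library sizes without 5 small RNA genes, removal of a smooth trend on transcript length, random lists matched also on length or GC content, removal of the median of neighbouring genes, and other dispersions for the authors' test.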

Results

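RNA sequencing compared a pair of human melanoma lines. SKMEL28 is a pigmented line with a mutant BRAF kinase, and SK-P8-2 is the line in which the gene of the microRNA miR-211 was deleted. Each line was profiled in culture and as xenografts in SCID mice, which lack functional T and B cells. The series addressed how loss of miR-211 alters melanoma metabolism and the response to BRAF inhibitors. The labels listed 6 libraries, 1 per line in culture and 2 xenografts per line, but the deposited xenograft table held 1 column per line. Both comparisons therefore set 1 column against 1 column, with no replicates, and folds below are described as higher or lower in the deletion line with no p-value. The columns summed to 63774334 reads in wild-type xenografts, 47797431 in deletion-line xenografts, 42451507 in wild-type cells and 42051915 in deletion-line cells. Intervals are exact 95% Clopper-Pearson intervals of the ratio of reads, and they cover counting error only, not the spread between cultures or tumours. The deletion was represented by 1 line, so a difference between the lines and an effect of the deletion were not separable.

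The targeted gene came first. MIR211 lies on the minus strand of chromosome 15 at 31065032 to 31065141 (hg38, GENCODE 29 annotation) and is nested inside TRPM1 (31001061 to 31161273), a cation channel gene of melanocytes that is transcribed with it. The mature miR-211-5p sequence is UUCCCUUUGUCAUCCUUCGCCU. MIR211 had 2 reads in wild-type and 0 in deletion-line xenografts, and 0 in each column of cells, all under the floor of 3 counts (0.0470 to 0.0713 CPM). The deletion was thus not checkable from these counts at this depth, and a short precursor is poorly captured in libraries of long RNA. The host gene TRPM1 was 1.12-fold higher in deletion-line xenografts (1.07 to 1.17; 60.8 against 68.0 CPM) and 1.15-fold lower in deletion-line cells (1.08 to 1.22; 52.2 against 45.5 CPM). The xenograft direction of TRPM1 flipped with the authors' RPKM values, to a log2 ratio of -0.15.

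In culture, the highest ratio was that of FMOD, which encodes the collagen-binding proteoglycan fibromodulin and was 56.9-fold higher in the deletion line (42.4 to 78.3; 1.06 against 60.4 CPM). PPARGC1A, a coactivator that drives mitochondrial biogenesis, was 5.07-fold higher (4.56 to 5.65), and the growth factor genes PDGFA and TGFA were 6.66-fold and 6.53-fold higher. PRKG2, a cGMP-dependent protein kinase, was 21.3-fold lower (16.4 to 28.0), the sulfotransferase gene CHST9 was 44.3-fold lower (26.2 to 81.5), and ALDH1L2, a mitochondrial folate enzyme, was 13.5-fold lower (9.56 to 19.8). Pigmentation genes were higher and genes of DNA replication and extracellular matrix were lower. Of 10713 genes with a mean of at least 5 CPM, 56 were at least 2-fold higher and 111 at least 2-fold lower on the (CPM + 1) scale. At a mean of at least 20 CPM the split was 25 higher and 30 lower.

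The other genes at the extremes in cells were FAM167A (7.83-fold higher), TMEM47 (7.30-fold), SERPINF1 (5.98-fold), which encodes a secreted anti-angiogenic serpin, the matrix glycoprotein gene EMILIN2 (4.15-fold), the drug efflux pump gene ABCB1 (3.95-fold) and CD74 (3.84-fold), the invariant chain of MHC class II. On the lower side, TENM4 was 19.3-fold lower, XYLT1, a xylosyltransferase of proteoglycan synthesis, was 9.96-fold lower, and FXYD3, a regulator of the sodium pump, was 8.70-fold lower. FAM129A, ANO5, PMP2 and PPP1R9A were 7.26-fold, 6.66-fold, 6.60-fold and 6.56-fold lower. Among the genes that were followed whatever their value, MITF, the master regulator of the melanocyte lineage, was 1.14-fold lower (1.12 to 1.15) and POU3F2, a transcription factor of the invasive state, was 1.69-fold lower (1.56 to 1.83). DUSP6, a phosphatase induced by ERK that switches ERK off, was 1.63-fold lower (1.55 to 1.71). TGFBR2 was within counting error (1.01-fold, 0.948 to 1.07), IGF2R was 1.16-fold higher, and PDK4 (0 reads in both columns) and KCNMA1 (0 against 3 reads) were at or under the floor.

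**Figure D1:**
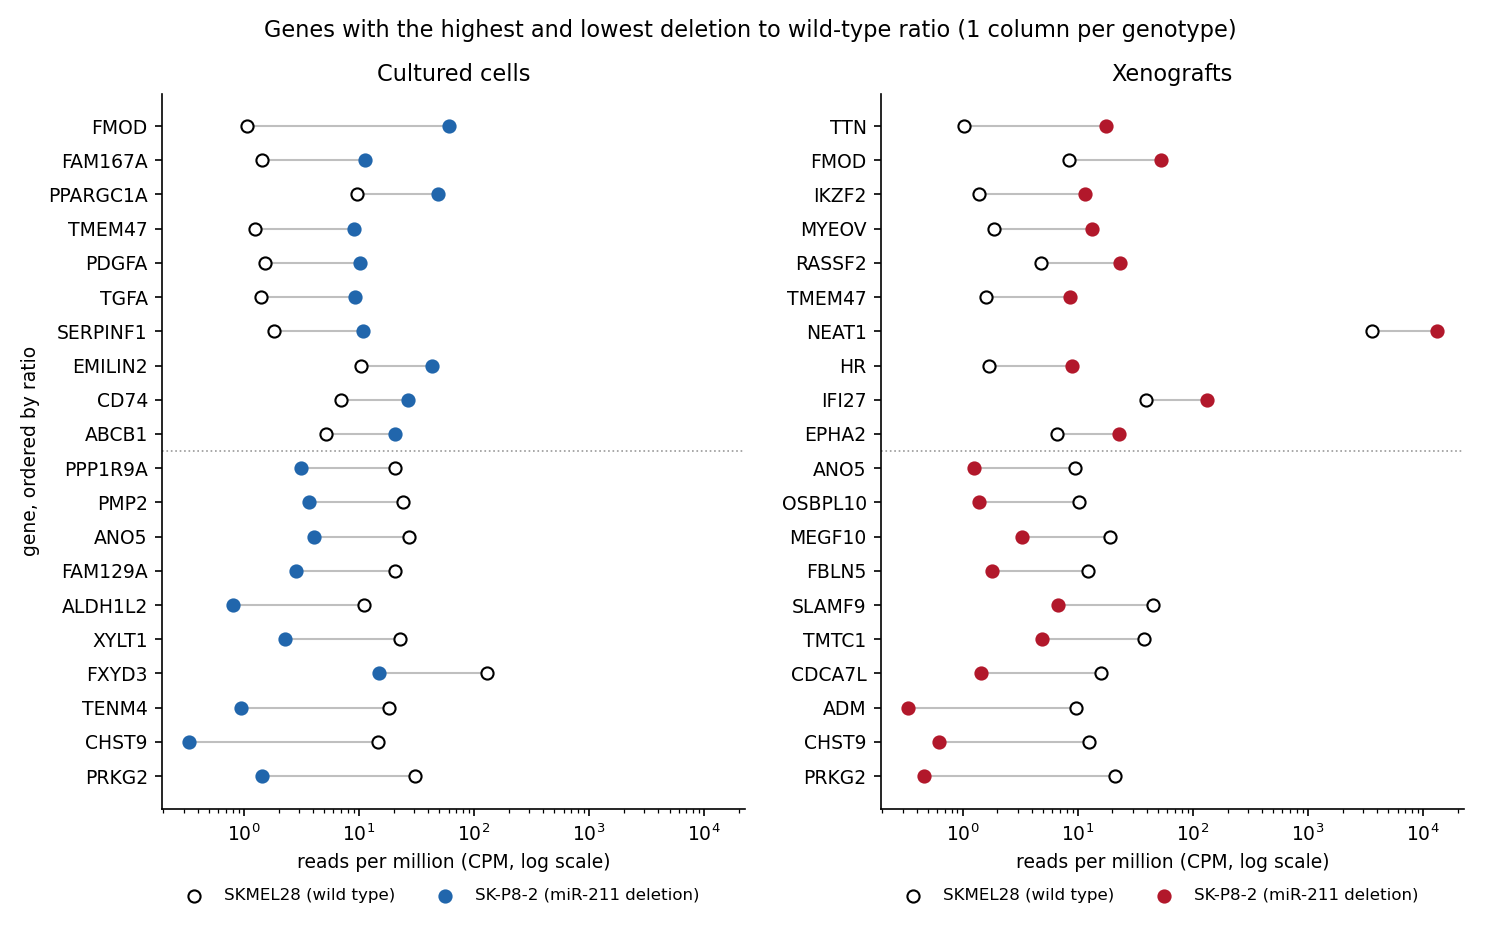
CPM (log scale) of the 10 genes with the highest and the 10 with the lowest deletion to wild-type ratio, in cultured cells and in xenografts; open points are SKMEL28, filled points are SK-P8-2, and each point is 1 deposited column with no replicates. FMOD went from 1.06 to 60.4 CPM in cells and from 8.37 to 52.8 CPM in xenografts, and PRKG2 was among the lowest ratios in both.

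Of 34 fixed gene lists with enough measured genes in cells, 8 had a median log2 ratio above and 5 below the central 95% of 10000 expression-matched random lists. Lists of independent genes would give 1.70 outside. Genes of a list can vary together, so with 1 column per line this excess does not separate a line difference from chance differences between cultures. The pigmentation and MITF programme stood at a median of 0.27 (percentile 100), with 19 of 25 measured genes higher and 8 by over 1.5-fold. Its leading members were PPARGC1A, the lipid carrier APOE (2.73-fold, 2.62 to 2.84) and OCA2, a melanosome transporter (2.02-fold). Lysosome and autophagy genes had a median of 0.30 (percentile 100; 20 of 21 higher), led by the proteases CTSD (2.17-fold, 2.15 to 2.19) and CTSA (1.53-fold). The matrix protease list (0.19, percentile 99.0; 9 of 14 higher) was led by MMP14, a membrane-bound collagenase (1.65-fold), and MMP2 (1.53-fold); at a mean of at least 20 CPM its percentile was 94.2. All 11 measured genes of MHC class I antigen presentation were higher (0.22, percentile 99.2), with HLA-F at 2.46-fold. Fatty acid oxidation (0.17, percentile 99.3; 14 of 19 higher) was led by ACADS (1.40-fold) and HADHB (1.31-fold). The tricarboxylic acid cycle (0.14, percentile 98.5; 16 of 23 higher) was led by IDH3G (1.43-fold) and SUCLA2 (1.39-fold). TGF-beta signalling (0.22, percentile 99.7; 9 of 14 higher) was led by PMEPA1 (2.57-fold) and ID2 (1.84-fold), but its percentile was 95.5 at a mean of at least 1 CPM and 74.2 at 20 CPM.

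The cell cycle genes of the cultured cells went in opposite directions by phase. DNA replication genes were lower in 26 of 26 (median -0.50, percentile 0), with CCNE2, the cyclin of S-phase entry, 3.24-fold lower (2.72 to 3.87), the helicase subunit MCM2 2.45-fold lower and RRM2 1.86-fold lower. Replication-dependent histones were lower in 17 of 17 (median -0.39, percentile 0), including HIST1H3D at 1.57-fold and HIST1H1B at 1.53-fold. G2 and M phase genes were higher in 18 of 24 (median 0.23, percentile 99.98), with CCNA2 at 1.46-fold, UBE2C at 1.46-fold and TOP2A at 1.38-fold. Extracellular matrix genes were lower in 8 of 9 (median -0.56, percentile 0), with the collagen-binding LUM 1.86-fold, the laminin LAMA4 1.78-fold and tenascin TNC 1.56-fold lower. The integrated stress response and amino acid supply list stood at -0.23 (percentile 0.18; 15 of 20 lower), led by ALDH1L2, the serine synthesis enzyme PSAT1 (3.08-fold lower) and CHAC1 (3.08-fold lower). The dedifferentiated or invasive melanoma programme stood at -0.21 (percentile 1.95; 11 of 14 lower), led by NT5E (2.39-fold lower), POU3F2 and THBS1 (1.63-fold lower); at a mean of at least 1 or at least 20 CPM its percentiles were 2.91 and 2.90, just inside the bound. Glycolysis (0.05, percentile 75.1), the hypoxia response (0.02, 57.4), the interferon response (0.08, 89.8) and ERK pathway output (-0.01, 46.1; mean 0.02) lay between the bounds. So did nuclear-encoded oxidative phosphorylation (0.09, 97.4), at percentile 99.96 among lists matched on transcript length and 92.1 among lists matched on GC content. The ratio in cells went with GC content (rho across genes 0.18) and not with length.

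In xenografts the deletion line had lower levels of glycolytic and hypoxia-response genes, and higher levels of interferon-response and MHC class I genes. ADM, a hypoxia-induced vasodilator peptide, was 29.1-fold lower (17.8 to 51.2; 9.74 against 0.335 CPM). GAPDH, a glycolytic enzyme, was 1.85-fold lower (1.84 to 1.86), and IFI27, an interferon-induced gene, was 3.38-fold higher (3.23 to 3.54). PRKG2 was 45.4-fold lower (29.9 to 72.8), CHST9 stood at 12.5 against 0.628 CPM, and FMOD was 6.31-fold higher (5.75 to 6.94). Of 10813 genes with a mean of at least 5 CPM, 75 were at least 2-fold higher and 49 at least 2-fold lower. That split depended on the scaling. It was 48 higher and 68 lower with TMM or RLE factors, 59 and 58 with upper-quartile scaling, and 11 and 62 with the authors' RPKM values. TMM factors lowered every xenograft log2 ratio by an amount of 0.12, and RPKM values shifted the median over genes by 0.24 in the same sense; the list percentiles below compare genes of the same columns.

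TTN, the giant sarcomere protein titin, had the highest ratio in xenografts (17.2-fold, 13.3 to 22.5; 1.02 against 17.5 CPM). Other skeletal muscle genes were higher with it in part. MYH2 stood at 0.0314 against 1.44 CPM, NEB at 1.76 against 4.31 CPM and DES at 0.517 against 1.49 CPM, while ACTA1 stood at 2.81 against 2.87 CPM. Strand use in the counting is not given in the sources used here, so TTN reads and those of its antisense partner were not told apart. The other highest ratios were those of IKZF2, a zinc finger factor of the Ikaros family (8.29-fold), MYEOV (6.99-fold), TMEM47 (5.38-fold), HR, a corepressor active in hair follicles (5.17-fold), the tumour suppressor RASSF2 (4.87-fold), the nuclear paraspeckle RNA NEAT1 (3.66-fold, 3.64 to 3.68; 3621 against 13258 CPM) and the ephrin receptor EPHA2 (3.49-fold). On the lower side were CDCA7L (11.1-fold), TMTC1 (7.71-fold), ANO5 (7.47-fold), the oxysterol-binding OSBPL10 (7.36-fold), the elastic fibre gene FBLN5 (6.79-fold), SLAMF9 (6.65-fold) and MEGF10, an engulfment receptor (5.84-fold). MITF was at 1.02-fold (1.01 to 1.04), a direction that flipped under every other scaling run, and DUSP6 was 1.04-fold lower. POU3F2 was 1.10-fold higher (1.01 to 1.20), which also flipped with RPKM values. IGF2R was 1.56-fold higher (1.54 to 1.59) and TGFBR2 1.31-fold higher (1.24 to 1.39). KCNMA1 had 89 against 83 reads (1.24-fold, 0.911 to 1.70), and PDK4 had 2 against 3, at or under the floor.

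Of 35 lists tested in xenografts, 8 were at the low and 7 at the high end, where lists of independent genes would give 1.75. Genes of a list can vary together, so here too this excess does not separate a line difference from chance differences between tumours. Glycolysis genes were lower in 19 of 22 (median -0.34, percentile 0), with ENO2 2.21-fold, TPI1 1.95-fold and GPI 1.57-fold lower. The hypoxia response was lower in 17 of 19 (-0.42, percentile 0), led by ADM, the collagen crosslinking enzyme LOX (2.53-fold), PDK1, which inhibits pyruvate dehydrogenase (2.27-fold), and the mitophagy receptor BNIP3 (2.24-fold). All 44 nuclear-encoded oxidative phosphorylation genes were lower (-0.33, percentile 0), NDUFA4 by 1.69-fold, COX6B1 by 1.66-fold, UQCRFS1 by 1.61-fold and NDUFA9 by 1.51-fold. With a trend on transcript length removed, that median was -0.030, against 0.05 for all genes, and 26 of the 44 were lower. Tricarboxylic acid cycle genes were lower in 17 of 23 (-0.16, percentile 0.44), with IDH2 1.49-fold and IDH1 1.43-fold lower and FH and SDHD each 1.23-fold lower; against length-matched lists the percentile was 3.45, inside the bound. DNA replication (-0.21, percentile 0; 22 of 26 lower) was led by MCM2 (1.97-fold), MCM7 (1.56-fold), RFC4 (1.51-fold) and CDC45 (1.43-fold). G2 and M phase (-0.21, percentile 0.04; 22 of 24 lower) was led by BIRC5, an inhibitor of apoptosis (1.43-fold), CCNB2 (1.37-fold), UBE2C (1.34-fold) and BUB1B (1.33-fold).

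Genes of antigen presentation and the interferon response were higher in the deletion-line xenografts. MHC class I antigen presentation was higher in 11 of 12 (median 0.49, percentile 100), with its transactivator NLRC5 at 2.02-fold (1.79 to 2.29), HLA-B at 1.70-fold, TAPBP at 1.56-fold and TAP2 at 1.46-fold. The interferon response was higher in 21 of 23 (0.39, percentile 100), with IFI44L at 2.32-fold, XAF1 at 1.93-fold and OASL at 1.76-fold. Targets of miR-211 and the related miR-204 reported in the literature were higher in 12 of 16 (0.26, percentile 99.4). NFAT5, a transcription factor of osmotic stress, led them at 2.06-fold (2.00 to 2.13), followed by RUNX2 at 1.70-fold, IGF2R and RAB22A at 1.32-fold; against length-matched lists the percentile was 96.1, inside the bound. With RPKM values 9 of the 16 were higher, at a median of 0.049. In cells the list lay between the bounds, with a median of 0.08 (percentile 86.5; 11 of 16 higher) and a mean of the other sign (-0.0066). The ERK5 and MEF2 pathway was higher in 9 of 9 (0.37, percentile 99.5), with KLF4 at 1.55-fold, the kinases MAP2K5 and MAPK7 at 1.37-fold and 1.32-fold, and MEF2D at 1.30-fold. WNT pathway genes were higher in 5 of 7 (0.31, percentile 97.6), led by TCF7L2 (1.48-fold), DKK1 (1.33-fold), SFRP1 (1.28-fold) and FZD7 (1.25-fold), with percentiles of 96.5 and 96.1 against length-matched and GC-matched lists. Lysosome and autophagy genes were higher in 15 of 21 (0.22, percentile 99.2), with CTSD at 1.51-fold, ULK1 at 1.46-fold, ATP6V1H at 1.40-fold and MCOLN1 at 1.36-fold; with RPKM values this median flipped to -0.020, at percentile 99.3. ERK pathway output (0.10, percentile 79.9), the kinases and phosphatases of the MAPK pathway (0.06, 56.6), pigmentation (0.10, 86.1) and the dedifferentiated programme (0.13, 84.5) lay between the bounds, although pigmentation was at percentile 99.5 among length-matched and 83.2 among GC-matched lists. The BCL2 family (0.21, 94.6) was likewise outside among length-matched lists alone (99.0). The numbers of members on each side depended on the scaling. With TMM factors 9 of 12 MHC class I, 20 of 23 interferon, 14 of 21 lysosome and 4 of 7 WNT genes were higher, and with RPKM values 8, 16, 10 and 4 were. ERK pathway output had a median of -0.02 with TMM factors and -0.12 with RPKM values.

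**Figure D2:**
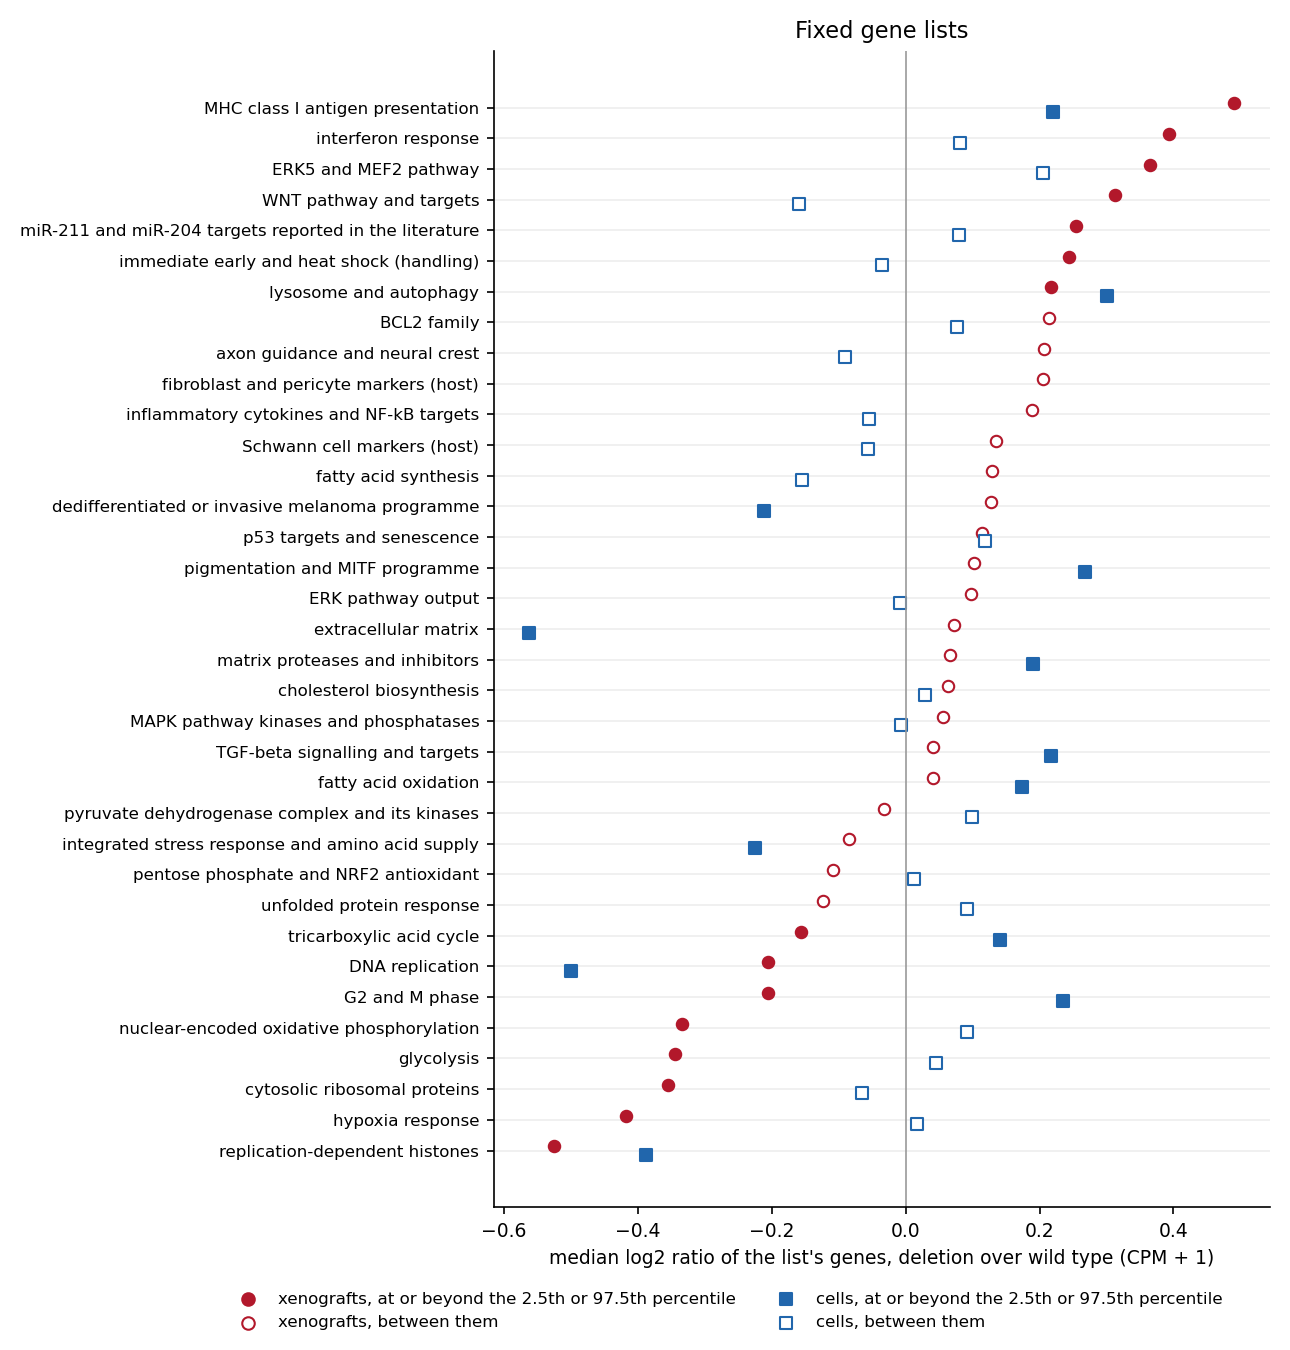
Median log2 ratio of (CPM + 1), deletion over wild type, of each fixed gene list in xenografts (circles) and cells (squares); filled symbols lie outside the central 95% of 10000 expression-matched random lists. Glycolysis stood at -0.34 in xenografts and 0.05 in cells, and DNA replication at -0.21 and -0.50.

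Features that can reflect sample quality differed between the lines in xenografts. The ratio went with transcript length in xenografts (Spearman rho across genes 0.47), from a median log2 ratio of -0.24 in the shortest to 0.29 in the longest of 10 equal bins of transcript length, and not in cells (rho 0.00378). Cytosolic ribosomal protein genes, which are short, were lower in 35 of 35 (-0.36, percentile 0; length-matched percentile 2.31), with RPS19 1.78-fold and RPL18 1.56-fold lower. Replication-dependent histones were lower in 17 of 17 (-0.52, percentile 0), with HIST2H3D 1.74-fold, HIST1H1D 1.66-fold, HIST1H3B 1.59-fold and HIST1H2AG 1.57-fold lower. Histones were also lower in 17 of 17 in cells (-0.39, percentile 0), so their shift was not particular to the xenografts and need not reflect sample quality. Immediate early and heat shock genes, which respond to handling of tissue, were higher in 15 of 19 (0.24, percentile 99.0), with EGR3 at 1.85-fold, EGR1 at 1.68-fold, ATF3 at 1.48-fold and BAG3 at 1.44-fold. With the length trend removed, the ribosomal protein median was -0.07 (22 of 35 lower) and the histone median -0.15. The same step left DNA replication at -0.12, the tricarboxylic acid cycle at -0.09, the reported miR-211 and miR-204 targets at 0.15 and the ERK5 and MEF2 pathway at 0.23. Immediate early and heat shock genes were higher in 12 of 19 with TMM factors and in 10 of 19 with RPKM values. Of the 15 lists outside the bounds, 12 were also outside among random lists matched on expression and length. Reads on stromal genes were present in xenografts. COL1A1 stood at 179 against 262 CPM there and at 0.259 against 0.214 CPM in cells. Host marker lists summed, wild type against deletion line, to 449.7 against 498 CPM for fibroblasts and pericytes, 208 against 221 CPM for macrophages and leukocytes, 12.4 against 18.7 CPM for endothelium, and 7.97 against 31.7 CPM for skeletal muscle. TTN alone made 1.02 against 17.5 CPM of the muscle sum. The sums were 1365 against 1535 CPM for Schwann cells, 129.6 against 120.4 CPM for keratinocytes, 8.81 against 6.03 CPM for adipocytes, 2.87 against 4.79 CPM for lymphocytes and 1.22 against 0.858 CPM for the erythroid list. The cultured cells themselves expressed 7 of 9 Schwann cell, 2 of 18 macrophage and leukocyte, 2 of 11 keratinocyte and 1 of 16 fibroblast and pericyte genes at a mean of at least 5 CPM. Reads of those histone, HLA and ribosomal protein genes that have near-identical copies are uncertain, since how shared reads were divided is not given in the sources used here.

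**Figure D3:**
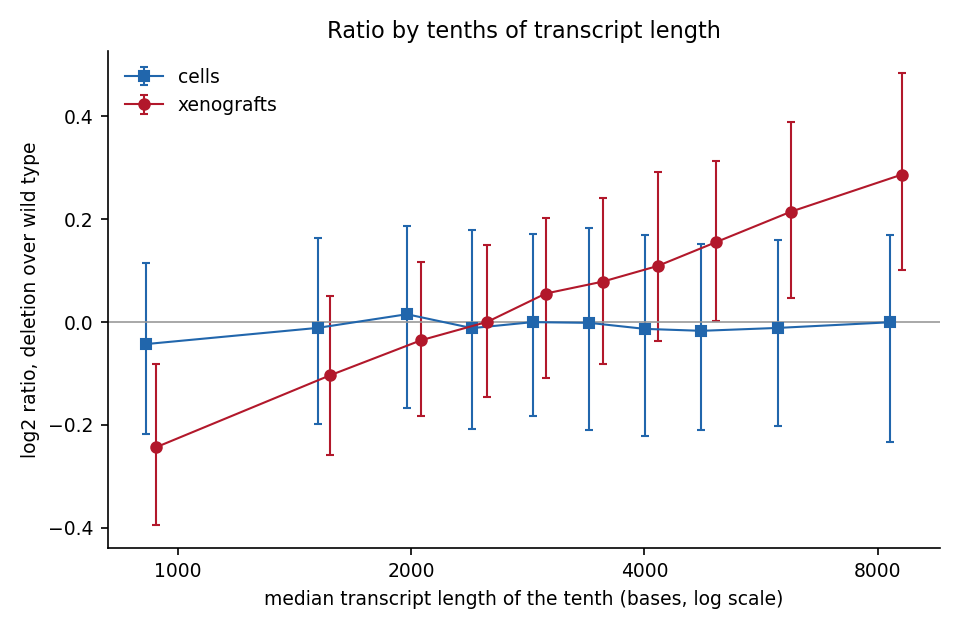
Median log2 ratio (deletion over wild type, points) and the range from the 25th to the 75th percentile of genes (bars) by 10 equal bins of transcript length in bases (log scale), in cells (squares) and xenografts (circles). The xenograft median went from -0.24 to 0.29, and the medians of cells were -0.04 in the shortest and 0.00 in the longest bin.

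The contrast in cells was then set against that in xenografts, to ask which differences held in both settings. FMOD, TMEM47, EMILIN2, EPHA2, ABCB1 and the kinase gene PRKCB were at least 2-fold higher in both, and PRKG2, CHST9, TMTC1, CDCA7L, ANO5 and the integrin gene ITGA4 were at least 2-fold lower in both. ABCB1 stood at 2.54 against 7.74 CPM in xenografts and at 5.21 against 20.6 CPM in cells. ITGA4 stood at 89.3 against 26.4 CPM and at 339.7 against 107 CPM. The 10 nearest expressed genes on each side of CDCA7L, TMTC1 and ITGA4 were lower as well, with median log2 ratios of -0.43, -0.58 and -0.43 in cells and -0.38, -0.19 and -0.26 in xenografts. PSAT1 and ALDH1L2, of serine and folate metabolism, were also lower in both. In all, 12 genes were higher and 22 lower in both tables, and 0 went at least 2-fold in opposite directions, where independent lists would share 0.148 and 0.314. Across 10274 genes, which are not independent replicates, Pearson's r was 0.45 and Spearman's rho 0.38. These counts cover only genes with a mean of at least 5 CPM in both settings. In xenografts that kept 77 of the 124 genes at least 2-fold different (39 of 75 higher, 38 of 49 lower). Of those 77, 63 had the same sign in cells. In cells it kept 124 of 167, of which 108 had the same sign in xenografts. The genes left out were not compared. The columns of the tables come from different libraries, so no control was shared, but both contrasts used the same pair of lines. The number of genes different the same way was 66 at a mean of at least 1 CPM and 7 at a mean of at least 20 CPM.

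**Figure D4:**
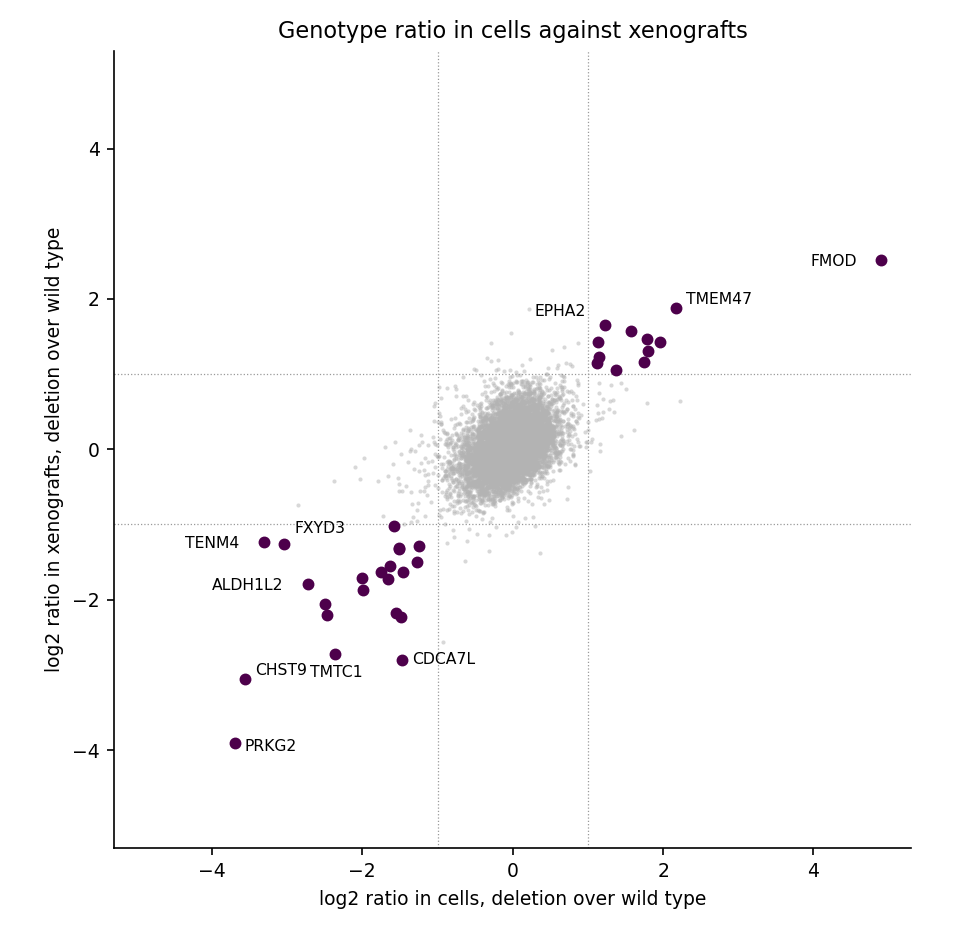
Log2 ratio of (CPM + 1), deletion over wild type, in cells (horizontal axis) against xenografts (vertical axis); grey points are the 10274 genes with a mean of at least 5 CPM in both tables, dark points the 34 genes at least 2-fold different the same way in both, and dotted lines mark 2-fold. The 12 genes higher in both and the 22 lower in both include FMOD and PRKG2, and the opposite corners hold 0 genes.

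Genes that carry a site for miR-211-5p in the 3' UTR were compared with genes that do not, since a lost microRNA no longer represses its targets. The 7-base sites AAAGGGA and AAGGGAA and the 8-base site AAAGGGAA were searched. In xenografts 2595 of 10195 genes had a site, and their mean log2 ratio lay 0.018 above that of genes without one within bins of 3' UTR length, at percentile 92.8 of 100000 permutations. In cells 2569 of 10164 genes had a site, with a difference of 0.0049 at percentile 65.6. With 8-base sites alone the differences were 0.019 and 0.032, at percentiles 81.7 and 94.3. Shuffled control sites of the same bases lay at percentiles 41.7 and 72.0 in xenografts and at 0.02 and 19.9 in cells, so in cells a shuffled site went further from the middle than the real one, while in xenografts the real one went furthest. With the length trend removed, the xenograft difference of the real sites was 0.0094, at percentile 80.7. No difference between genes with and without sites was thus detectable, and genes are not independent replicates. Mature miR-211 was not measured here, so how much repression could be lost is not known.

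The authors' deposited table gives a fold, p-value and FDR per transcript. At an FDR under 0.05 the authors' deposited table called 1221 of 57949 transcripts in xenografts (624 higher, 597 lower) and 1466 in cells (592 higher, 874 lower). Of the genes that differed at least 2-fold as a whole, 64 of 124 in xenografts and 104 of 167 in cells had such a transcript in the authors' deposited table. In that table FMOD (higher), PRKG2 and CHST9 (both lower) were called in xenografts and in cells, while the authors' deposited table called 1 NEAT1 transcript higher and 1 lower in xenografts. An exact test on the rounded reads with a fixed dispersion of 0.05 gave the p-values of the authors' deposited table within 0.001 for 98.0% of transcripts in xenografts and 99.998% in cells. Those p-values therefore rest on an assumed spread, not on one measured between samples. With 0.16 in place of 0.05 the calls numbered 50 in xenografts and 47 in cells.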

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

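The comparison of melanoma cell share and the correlation of adjacent windows were tests chosen after the result had been seen, and the length-matched lists, the length trend and the other dispersions were added after the data were examined.

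A pair of gene lists lay at opposite ends in cells and xenografts. The tricarboxylic acid cycle list had a median log2 ratio of 0.14 in cells and -0.16 in xenografts, and the G2 and M phase list 0.23 in cells and -0.21 in xenografts. Among length-matched lists the tricarboxylic acid cycle list was inside the bound in xenografts (percentile 3.45). With 1 column per line in each setting, the difference was not tested.

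In deletion-line xenografts the glycolysis, hypoxia, oxidative phosphorylation and ribosomal protein lists were low and the interferon and MHC class I lists high, while log2 ratios went with transcript length (rho 0.47), as RNA degradation or library preparation could cause. Among random lists matched on length as well, glycolysis and the hypoxia response stayed at percentile 0, oxidative phosphorylation at 0.54 and the interferon response and MHC class I at 100. This argues against length as the whole explanation for glycolysis, hypoxia, interferon and MHC class I. For oxidative phosphorylation it cannot decide. The list's median length of 851 bases lay below the 924 of the shortest bin, within which the trend can continue. With the length trend removed, the medians were -0.28 for glycolysis, -0.42 for hypoxia, 0.48 for interferon and 0.54 for MHC class I, but -0.03 for oxidative phosphorylation and -0.07 for ribosomal proteins, against 0.05 for all genes. For ribosomal proteins length cannot be told apart from another cause, since the percentile of 2.31 (2.02 to 2.61, from the number of random lists) spans the bound. A lower share of melanoma cells would lower pigmentation genes alike, yet their median lay 0.45 above that of glycolysis (bootstrap 0.26 to 0.69). This cannot decide the question, since pigmentation genes were already higher in deletion-line cells (median 0.27), which could mask a lower share. Column sums made 72.9% of the implied read totals in wild-type and 61.7% in deletion-line xenografts, and what the rest was is not known. The melanoma cell share thus stays open. The regional differences between the lines described in the next paragraph were not tested as a cause for these lists. In cells the glycolysis list had a median of 0.05. The deletion itself, regional differences, and differences in tumour size or oxygen supply stay open and untested.

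The lines differed alike in cells and xenografts both in 34 single genes and in whole regions, with medians of windows of 20 neighbouring genes correlated at 0.68 between the tables against 0.20 to 0.36 in 1000 random gene orders. Adjacent windows correlated at 0.80 (random orders -0.09 to 0.09), which is consistent with a regional copy number difference between the lines, and removing length and GC trends left 0.74 between the tables (random orders 0.23 to 0.39), which argues against those trends. Of the 34 genes, 1 (2.94%, 0.0744 to 15.3) had neighbours with medians at least 0.3 the same way in both tables. That count cannot decide on a regional cause, since only 6 of all 491 windows reached 0.3 in both. Neighbours of others were lower in both but short of that bar in at least 1 table (in cells and xenografts TFPI2 -0.59 and -0.24, TMTC1 -0.58 and -0.19, ITGA4 -0.43 and -0.26, IGFBP3 -0.29 and -0.22, EMC10 -0.26 and -0.26, FXYD3 -0.23 and -0.34). Neighbours of PRKG2 and CHST9 were not lower in either table. The printed medians were smaller in size than the genes' own differences of at least 2-fold, and a regional part stays open. Of the 12 genes higher in both, 9 (75%, 42.8 to 94.5) carried a miR-211-5p site against 34.6% in sets matched on 3' UTR length (percentile 99.92), while shuffled sites occurred in 5 and 4 of them (percentiles 59.7 and 23.2), so loss of repression may contribute to this set. The evidence is weak, since genes with sites did not differ detectably from other genes. A shuffled site also reached percentile 0.02 among all genes in cells, so an extreme percentile can arise without a real site. Any other difference between a single deletion line and its parent remains open and untested.

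In the authors' deposited table, 69.4% of the calls in xenografts and 63.6% of those in cells lay in genes that differed by under 1.5-fold as a whole. Gene ratios here were on the CPM + 1 scale with no expression filter, and the added 1 CPM shrinks the ratios of low genes and raises this share. Only 655 of the 1221 calls in xenografts and 839 of the 1466 in cells lay in genes with a mean of at least 5 CPM. The share under 1.5-fold was 56.0 percentage points (45.8 to 63.2) higher in genes with 2 or more transcripts than in genes with 1 in xenografts, and 63.3 points (56.9 to 67.0) higher in cells. The design largely fixed this outcome, since the smallest call in the authors' deposited table had a log2 fold of 1.58 in xenografts and 1.54 in cells. The call of a gene with 1 transcript is the gene itself, apart from scaling and the added 1 CPM. Of such calls, 13 of 77 in xenografts and 5 of 105 in cells still lay under 1.5-fold. The authors' deposited table called transcripts both higher and lower in 67 genes in xenografts and 74 in cells. Reads shared between transcripts of a gene and true switches between transcripts therefore cannot be told apart here, and no biological explanation was tested.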

How the results depend on the processing

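RPKM values, the length trend, neighbouring genes and other dispersions were alternatives chosen after the data were seen. No paired analysis was possible because each table has 1 column per line, and for the same reason the planned quasi-likelihood, DESeq2, voom, camera, fry, replicate block, leave-one-out and interaction fits were not run; the stricter filter of 5 CPM was already the one used. Named genes that had been called kept their direction, while uncalled TRPM1, MITF and POU3F2 in xenografts changed sign under some scalings. Sizes moved beyond the counting interval in 330 values of the 85 named xenograft results and not in 435, and in 58 values of the 64 named results of cells and not in 390; that interval covers counting error only, and the cause was not tested. Of 15 list results in xenografts and 13 in cells, 1 turned. That was the lysosome list in xenografts, at -0.020 with RPKM values. Xenograft genes higher numbered 48 with TMM and 48 with RLE factors, where 97 of the 124 genes were shared with the count reported. RPKM values gave 73 genes (11 higher), 47 of them shared. With no filter there were 215 (127 higher, 88 lower), because more genes entered. The authors' deposited table gave 1221 transcripts (624 higher, 597 lower), and the same 1221, 624 and 597 with a 2-fold rule added. In cells, RPKM values gave 105 genes (63 lower). A mean of at least 1 CPM gave 295 (92 higher, 203 lower) and of 20 CPM 55 (25 and 30), as more or fewer genes entered. A 1.5-fold rule gave 805 (254 and 551) and a 4-fold rule 24 (7 and 17). The authors' deposited table gave 466 transcripts of at least 5 CPM by its folds (201 higher, 265 lower). Genes different the same way in both settings numbered 66 at 1 CPM and 7 at 20 CPM. The correlation between settings was 0.51 with the length trend removed and 0.38 with the neighbouring genes' median removed. The seed site difference in cells was 0.032 with 8-base sites. The authors' calls numbered 2996, 362 and 50 in xenografts and 3143, 363 and 47 in cells at dispersions of 0.025, 0.1 and 0.16. RPKM values divide by larger read totals. The column sums made 72.9% and 61.7% of them in wild-type and deletion-line xenografts, and 84.0% and 84.9% in cells. These shares account for the median difference between CPM and RPKM log2 ratios, 0.24 in xenografts and -0.015 in cells (CPM minus RPKM, no pseudocount). The part played by adding 1 RPKM was not separated. Apart from this scaling and from filters, fold rules and dispersions, whose construction sets the count, the cause was not tested. Depth limits the low genes: MIR211 and PDK4 in both tables and KCNMA1 in cells were at or under the floor of 3 counts.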

Other observations

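The genes, chromosomes and windows in this part were chosen after their values were seen, and no test of an explanation is added here.

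Several MHC class II genes, which formed no fixed list and were picked after their values were seen, were higher in the deletion line in culture. CD74, the invariant chain that escorts class II molecules, was 3.84-fold higher (3.38 to 4.38), HLA-DRA 3.67-fold (3.19 to 4.24), HLA-DPA1 3.52-fold (3.31 to 3.75), HLA-DPB1 4.27-fold (3.50 to 5.24) and HLA-DRB1 6.98-fold (3.79 to 14.1), and the peptide exchange factor subunit HLA-DMA 1.42-fold (1.29 to 1.56). HLA-DMB had 653 against 842 reads and HLA-DOB 73 against 86, while HLA-DQA1, HLA-DQB1 and HLA-DOA had at most 33 reads in a column. Their transactivator CIITA had 34 against 49 reads, a ratio whose interval (0.920 to 2.32) includes no difference; in xenografts it had 23 against 43 reads, 2.49-fold higher (1.47 to 4.34). In xenografts HLA-DPA1 was 1.59-fold higher (1.42 to 1.78), CD74 was within counting error (1.02-fold lower, 0.839 to 1.25), as was HLA-DMA (1.05-fold lower, 0.807 to 1.38), HLA-DMB was lower at 80 against 28 reads, HLA-DOB had 118 against 168, and HLA-DRA, HLA-DRB1 and HLA-DPB1 had at most 3 reads. Where an HLA gene has near-identical copies, as HLA-DRB1 does, the split of reads between them is uncertain.

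Outputs of the ERK pathway did not go one way in culture, with 10 higher and 10 lower. DUSP6 and SPRY4 stood at 94.3 against 58.0 CPM and 67.3 against 34.3 CPM, while DUSP4 stood at 437 against 545 CPM, PHLDA1 at 524 against 719 CPM and MAFF at 66.3 against 131 CPM. In xenografts the list lay between the bounds (percentile 79.9), with 18 of 23 genes higher but 11 of 23 with TMM factors. DUSP5 stood at 18.2 against 34.9 CPM there and SPRY4 at 128 against 205 CPM. BRAF itself was at 1.00-fold in cells (0.918 to 1.10) and 1.08-fold lower in xenografts (1.00 to 1.16). The melanocyte receptor EDNRB was higher in both, at 81.4 against 149 CPM in cells and 35.3 against 95.8 CPM in xenografts.

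Chromosome 7 stood apart from the others. Its 465 genes had a median log2 ratio of -0.31 in cells and -0.19 in xenografts, and 20 of its 23 windows of 20 genes were lower in both. The next lowest chromosome was 19, at -0.11 and -0.10 over 630 genes. Of 491 windows, 6 had medians of -0.3 or lower in both tables, including 1 on chromosome 6 from 26026815 to 26217483 that covers the histone cluster, and 0 had medians of 0.3 or higher. ABCB1, on chromosome 7, differed from that direction and was higher in both tables. MET, on the same chromosome, was 1.04-fold higher in cells (0.989 to 1.10). In xenografts MET was 1.44-fold lower (1.39 to 1.49), the direction of the chromosome.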
